A study of Danio rerio with 4 samples.

How the data were processed

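DNA methylation was measured by reduced representation bisulfite sequencing in whole zebrafish embryos at 24 hours after fertilisation, from a mixed AB and Tübingen background. The labels give 2 groups of 2 libraries: wild type embryos, and embryos injected at the single-cell stage with Cas9 and guides against tet1, tet2 and tet3. Such injected embryos are the generation that received the editing reagents and can be mosaics of differently edited cells. The tet genes encode enzymes that oxidise 5-methylcytosine. Per the labels' protocols, 500 ng of DNA was digested with MspI, which cuts at CCGG and so enriches CpG-rich fragments, with 0.025 ng of unmethylated lambda phage DNA added. The DNA was then converted with bisulfite, amplified by 13 PCR cycles and sequenced as 150 bp read pairs. Bisulfite does not separate 5-methylcytosine from 5-hydroxymethylcytosine, the first product of the Tet enzymes.

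The deposited files list 1 CpG per line with counts of methylated and unmethylated reads, per the file headers and values. The authors also gave a percent, which is the whole part of 100 times the methylated count over both counts at 100% of the listed CpGs. The percent was recomputed here from the counts. Trim Galore, MethylDackel and GRCz10 were named in the submitters' processing notes without versions, and the file headers give danRer10, another name of that build. The aligner and any filters were not given in the sources used here. All coordinates are on danRer10 and count from 1.

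The 4 files were compared before any analysis. The file of knockout replicate 1 was identical to the file of wild type replicate 1, and the header line inside both carries a wild type replicate name. Its content therefore belongs to no group with certainty and is called the shared file. As fixed before the data were examined, no main comparison between groups used it in a test. Knockout replicate 2 was compared with wild type replicate 2, 1 library against 1, and the shared file served as a yardstick for how far 2 libraries lie apart. No difference between the 2 groups has a replicate check, and the planned permutation tests and the planned fit of 2 against 2 libraries were not made. The exceptions are fits added after seeing the data, in which the shared file was read as wild type or as knockout. Their p-values hold only if that reading of the file is right.

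Lambda and mitochondrial CpGs were used only to measure conversion. Nuclear CpGs with at least 10 reads in each of the 3 distinct libraries were kept, 935663 in all. Levels are unweighted means over these CpGs. Methylation classes were below 20%, 20 to 80% and above 80% in the mean of the 3 distinct libraries. Density classes counted listed CpGs within 100 bp on either side, the CpG itself included. Windows were 200 bp, did not overlap, and held at least 3 such CpGs, with counts summed, which gave 134500 windows. A window or CpG was counted as higher or lower at a difference of at least 20 percentage points. That size stood among the alternatives written before the data were examined, and it replaced the planned adjusted p as the main criterion after the identical files were found.

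The rule for named windows was adapted for the same reason. In each direction, it took the 10 windows with the largest difference between knockout replicate 2 and wild type replicate 2 among those with a Benjamini-Hochberg adjusted p below 0.05. That p is from a two-sided Fisher's exact test on the reads of these libraries, and it compares the libraries, not the conditions. Knockout replicate 2 also had to lie outside the range of both other libraries. At most 1 window per 10 kb was taken, on placed chromosomes only. Reads of 1 fragment cover several CpGs, and it is not known whether PCR copies were removed. Intervals (95%, Wilson for windows, exact for lambda) and Fisher p-values therefore treat dependent counts as independent. They cover counting error only and are too narrow.

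Because no genome or gene annotation of danRer10 was used here, windows were not assigned to genes. Promoters, gene bodies, genomic features and the 13 gene lists fixed beforehand were not analysed, and editing at the tet loci was not measured. For the same reason the embryos' loss of tet function was taken from the labels alone.

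Alternatives varied the coverage minimum (5 and 20 reads), a coverage maximum (99.9th percentile), the window width (100 and 500 bp), the CpGs per window (1 or more), the size of the difference (10 points), the class borders (10 and 90%), the weighting and the library left out. Chosen after seeing the data were thinning of each CpG to the lowest of its 3 coverages, a shift of all libraries to an equal median on the logit scale (levels held within 0.5 and 99.5%), the demand that a window lie apart from both other libraries, and a limit of 1.5-fold on the change in coverage. Also chosen then were fits with 1 library set against the other 2: edgeR's quasi-likelihood test, limma on the log2 ratio of methylated to unmethylated counts with 2 added to each, and a quasi-binomial model. These assume that the lone library varies as the others do.

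The rules were tested on 20000 simulated windows drawn with the coverage of the real ones and an overdispersion of 0.0097, estimated between the shared file and wild type replicate 2. Of 200 windows raised by 40 points in knockout replicate 2, the 20-point rule recovered 99.0%, and of 200 raised by 25 points 66.0%. It also counted 19 unchanged windows as higher (0.097% of those unchanged). Fisher's exact test called 678 of them higher (3.46%). For the windows raised by 40 points, edgeR, limma and the quasi-binomial model recovered 0 at an adjusted p below 0.05. At an unadjusted p below 0.05 they recovered 94.5%, 95.0% and 89.5%. The simulated windows were noisier than the data, so they cannot show why these fits gave few calls there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and limma 3.58.1 were used.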

Results

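Methylation at CpG sites was measured in 4 deposited libraries of whole zebrafish embryos, 2 labelled wild type and 2 labelled tet1/2/3 knockout. The files of wild type replicate 1 and knockout replicate 1 were identical in 100% of their lines, so the series held 3 distinct libraries: the shared file, wild type replicate 2 and knockout replicate 2. In the other pairs of libraries, at most 1.89% of CpGs with at least 10 reads in both had the same counts. The shared file listed 7360703 CpGs with 86952544 CpG calls in total, wild type replicate 2 listed 5813180 with 52002161, and knockout replicate 2 listed 6191060 with 46875223. Many CpGs were covered thinly: 43.6%, 46.5% and 48.8% of those listed had a single read. The differences below are between single libraries and have no replicate check.

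Unmethylated DNA set the background of the assay. Of the cytosines in lambda CpGs, 0.181% (95% interval 0.176 to 0.186) read as methylated in the shared file, 0.201% (0.195 to 0.207) in wild type replicate 2 and 0.192% (0.186 to 0.198) in knockout replicate 2. Mitochondrial CpGs gave 0.203%, 0.191% and 0.157%.

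The first comparison asked whether embryos injected against the 3 tet genes differed in overall methylation. Over 935663 nuclear CpGs with at least 10 reads in all 3 libraries, the mean level was 84.8% in the shared file, 84.7% in wild type replicate 2 and 85.3% in knockout replicate 2. Knockout replicate 2 lay 0.635 points above wild type replicate 2 and 0.492 points above the shared file, and the shared file lay 0.143 points above wild type replicate 2. With reads summed over CpGs, the first difference was 0.407 points. Without wild type replicate 1, so with the shared file counted as knockout, it was 0.389 points. Without knockout replicate 2, only the shared file against wild type replicate 2 remained, at 0.143 points. Over every CpG with at least 10 reads in the library itself, the order differed: the mean was 86.1% in the shared file, 85.1% in wild type replicate 2 and 85.5% in knockout replicate 2.

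The difference was found on all 25 chromosomes, where knockout replicate 2 exceeded wild type replicate 2 by 0.494 to 0.805 points and the shared file by 0.381 to 0.677 points. The shared file also exceeded wild type replicate 2 on all 25, by 0.0323 to 0.248 points. On chromosome 4, the bins between 30000001 and 80000000 had levels of 91.2% to 94.1% in the 3 libraries, and knockout replicate 2 exceeded wild type replicate 2 there by 0.0941 to 0.650 points. In the first bin of that chromosome (1 to 10000000) the level was 78.7% in wild type replicate 2, with a difference of 0.943 points.

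**Figure D1:**
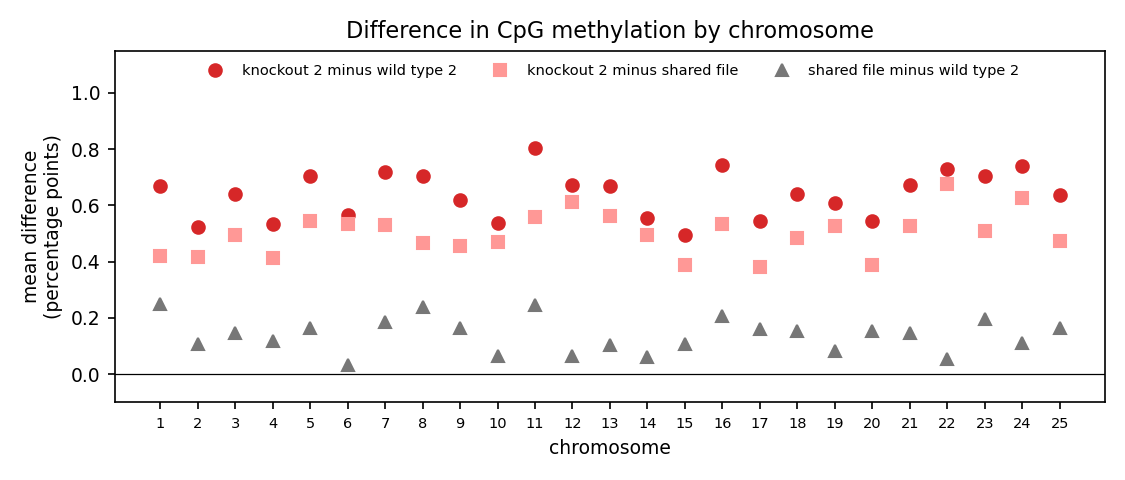
Mean difference in CpG methylation in percentage points (vertical axis) on each of the 25 chromosomes (horizontal axis), for the 3 pairs of distinct libraries, 1 point per pair and chromosome. Knockout replicate 2 lay above wild type replicate 2 by 0.494 to 0.805 points, and the shared file lay above it by 0.0323 to 0.248 points.

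CpGs were split by methylation level. In the 41590 CpGs of 20 to 80%, the mean was 57.9% in the shared file, 56.7% in wild type replicate 2 and 60.1% in knockout replicate 2. The last lay 3.40 points above wild type replicate 2 and 2.15 points above the shared file, while those 2 differed by 1.25 points. In the 86892 CpGs below 20%, the means were 1.12%, 1.09% and 1.12%, and knockout replicate 2 differed from wild type replicate 2 by 0.0295 points. In the 807181 CpGs above 80%, knockout replicate 2 was 0.558 points above wild type replicate 2 and 0.460 points above the shared file. In percentage points the difference was widest in the class of 20 to 80%. On the logit scale, knockout replicate 2 exceeded wild type replicate 2 by 0.0851, 0.135 and 0.195 in the bins of 20 to 40, 40 to 60 and 60 to 80%, and by 0.144, 0.104 and 0.155 in those of 80 to 90, 90 to 95 and 95 to 100%. Against the shared file the widest logit difference was 0.323, at 95 to 100%. The shared file was low in that bin against wild type replicate 2 too, with a logit difference of -0.168. In narrower bins the order did not hold throughout: at 80 to 90% knockout replicate 2 lay 1.69 points above wild type replicate 2, but its difference from the shared file was -0.504 points. When the class was defined by the shared file and wild type replicate 2, the difference in the 20 to 80% class was 5.19 points. Wild type replicate 2 then both sets the class and enters the difference, which can by itself raise that value. In the class over the 3 libraries, the difference was 1.25 points without knockout replicate 2 and 2.15 points without wild type replicate 2.

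**Figure D2:**
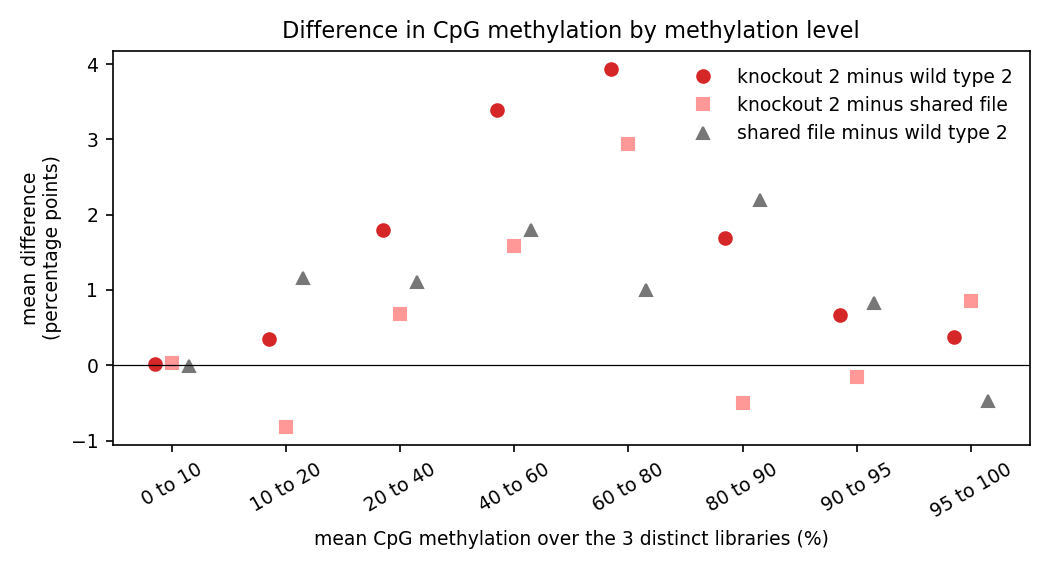
Mean difference in percentage points (vertical axis) for CpGs binned by their mean methylation over the 3 distinct libraries (horizontal axis, percent), 1 point per pair of libraries and bin. The difference between knockout replicate 2 and wild type replicate 2 was 3.94 points at 60 to 80% and 0.019 points below 10%, and knockout replicate 2 lay below the shared file in the bins of 10 to 20%, 80 to 90% and 90 to 95%.

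CpG density was compared next, since MspI fragments span CpG islands and sparser DNA. Knockout replicate 2 exceeded wild type replicate 2 by 0.971 points at 60625 CpGs with 1 to 3 listed CpGs within 100 bp on either side, and by 0.830 points at 303859 CpGs with 4 to 7. The difference was 0.593 points at 411410 CpGs with 8 to 14. At the 159769 CpGs with 15 or more it was 0.246 points, and -0.198 points with reads summed over CpGs. In the same order of classes, knockout replicate 2 exceeded the shared file by 0.881, 0.711, 0.442 and 0.0575 points, which are the values without wild type replicate 2. The shared file exceeded wild type replicate 2 by 0.0898, 0.119, 0.151 and 0.189 points, which are the values without knockout replicate 2. Among CpGs of 20 to 80% methylation, the difference from wild type replicate 2 was 4.48 points at 4 to 7 listed CpGs, with 3.34 points from the shared file. It was 3.40 points at 1 to 3, 3.28 points at 8 to 14 and 0.696 points at 15 or more, so it was not widest at the lowest density. At 15 or more, knockout replicate 2 differed from the shared file by -1.06 points.

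Windows of 200 bp were then compared to find regions that differed. Of 134500 windows, 665 lay at least 20 points higher in knockout replicate 2 than in wild type replicate 2 and 174 at least 20 points lower, so 79.3% were higher. With all libraries shifted to an equal median the counts were 512 and 248, and 67.4% were higher. The yardstick pair was not at zero: the shared file had 233 windows at least 20 points above wild type replicate 2 and 120 below it. Knockout replicate 2 had 490 windows above the shared file and 164 below it. The shared file had the most reads, which makes the yardstick unequal. With every CpG thinned to the same coverage, the yardstick pair gave 308 higher and 177 lower windows. Knockout replicate 2 against wild type replicate 2 then gave 715 and 183, so the counts of lower windows were close. Of the 665 higher windows, 355 went from 20 to 80% in wild type replicate 2 to above 80% in knockout replicate 2, 273 stayed within 20 to 80%, 36 went from below 20% to that range, and 1 went from below 20% to above 80%. Averaged into the wild type side, the shared file left 425 higher and 119 lower windows. Averaged into the knockout side, it left 289 and 62.

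In 240 windows knockout replicate 2 lay at least 20 points above both other libraries, and in 59 at least 20 points below both. The counts above and below both others were 24 and 121 for wild type replicate 2, and 43 and 43 for the shared file. With every CpG thinned to the same coverage in each library, the windows above both others numbered 246 for knockout replicate 2, 29 for wild type replicate 2 and 50 for the shared file. The 240 windows averaged 47.9% in the shared file, 45.2% in wild type replicate 2 and 76.5% in knockout replicate 2, and 233 of them had a mean level of 20 to 80%, a range that a rise of 20 points favours. In 226 of the 240, every CpG was higher in knockout replicate 2 than in wild type replicate 2. Choosing windows on their summed level favours this, as do reads that cover several CpGs. Coverage relative to each library's median changed over 2-fold between these libraries in 9.58% of the 240 windows (95% interval 6.47 to 14). It did so in 10.2% of the 59 windows below both others and in 4.15% of all windows of 20 to 80%.

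CpGs around these windows were also compared, although those nearest can lie on the same reads as the window that was selected. CpGs 1 to 200 bp outside the 240 windows were 20.9 ± 1.05 points (SEM over 172 windows) higher in knockout replicate 2 than in wild type replicate 2, those over 200 and up to 500 bp away 6.35 ± 2.02 points (36 windows), and those over 500 and up to 1000 bp away -0.0379 ± 0.818 points (29 windows). Farther out it was 1.67 ± 0.722 points up to 2000 bp (47 windows) and 1.53 ± 0.437 points up to 5000 bp (86 windows). Around all windows of 20 to 80% the values at these distances were 0.887 ± 0.141 and 1.08 ± 0.0899 points. Of the 233 windows of intermediate level, 2.58% (95% interval 1.19 to 5.50) lay within 2 kb of a window below 20%, against 3.70% (3.29 to 4.16) of all 7301 intermediate windows.

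**Figure D3:**
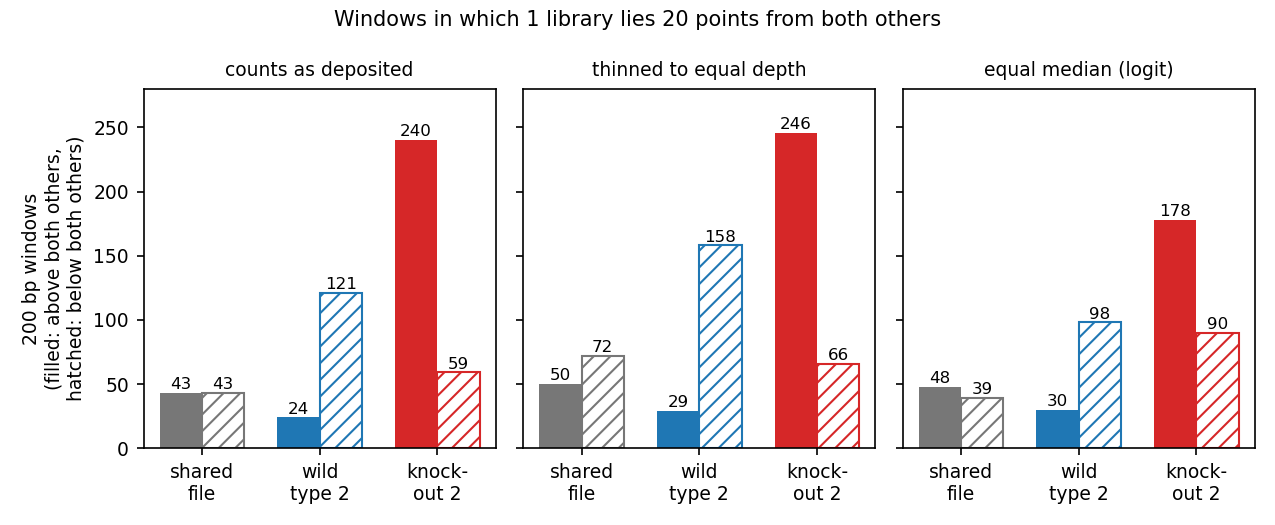
Number of 200 bp windows (vertical axis) in which 1 library lay at least 20 percentage points above both others (filled bars) or below both others (hatched bars), for the 3 distinct libraries. Knockout replicate 2 had 240 and 59 with counts as deposited (left), 246 and 66 at equal depth (middle) and 178 and 90 at equal medians (right).

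The 10 named windows that were higher in knockout replicate 2 differed from wild type replicate 2 by 56.1 to 74.2 points, and all 10 lay at least 20 points above the shared file. Each held 3 to 9 CpGs, all of them higher in knockout replicate 2, which the choice of windows favours. In 6 of the 10 the shared file also lay at least 20 points from wild type replicate 2. The largest difference was on chromosome 7 at 23206801 to 23207000, with 87.5% (95% interval 76.4 to 93.8) in knockout replicate 2, 13.3% (9.17 to 18.9) in wild type replicate 2 and 53.1% (41.1 to 64.8) in the shared file. Coverage per CpG was 14 reads, 47 reads and 16 reads in that order. On chromosome 8, the window at 41248401 to 41248600 had 93.8% (87.0 to 97.1) in knockout replicate 2, 20.7% (16.6 to 25.4) in wild type replicate 2 and 31.0% (27.7 to 34.6) in the shared file, at 16, 54 and 115 reads per CpG.

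In 4 of the 10 windows the shared file lay less than 20 points from wild type replicate 2. They include the window on chromosome 8 and 3 more. On chromosome 18 at 20330201 to 20330400, knockout replicate 2 had 98.8%, wild type replicate 2 had 42.7% and the shared file 40.9%, at 28, 124 and 137 reads per CpG. On chromosome 4 at 52417801 to 52418000, the levels were 88.7%, 31.4% and 34.3%, with 32 reads per CpG in knockout replicate 2 and at least 108 in the others. On chromosome 11 at 18474801 to 18475000, they were 79.8%, 18.8% and 29.0%.

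At the other named higher windows the shared file lay between the other libraries, at least 20 points above wild type replicate 2. On chromosome 11 at 18549801 to 18550000, it had 33.6%, against 76.3% in knockout replicate 2 and 13.3% in wild type replicate 2. On chromosome 13 at 22877201 to 22877400, it had 28.8%, against 72.8% and 8.25%. On chromosome 22 at 13003601 to 13003800, it had 56.2%, against 87.7% and 20.0%. On chromosome 7 at 33891801 to 33892000, it had 65.6%, against 86.7% and 24.4%. Coverage per CpG there was 15 reads in knockout replicate 2, 68 in wild type replicate 2 and 78 in the shared file. At the window on chromosome 11 at 18549801 it was alike, with 10 to 11 reads in knockout replicate 2 and 10 in wild type replicate 2.

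Among the 10 named lower windows, differences ran from -75.1 to -39.5 points, and 7 of the 10 lay at least 20 points from the shared file. On chromosome 15 at 14313801 to 14314000, 9 CpGs had 3.03% (95% interval 1.60 to 5.66) in knockout replicate 2, 78.1% (74.5 to 81.2) in wild type replicate 2 and 82.2% (78.1 to 85.7) in the shared file, at 33 reads or more per CpG. On chromosome 4 at 52739201 to 52739400, knockout replicate 2 had 34.1% at 11 reads per CpG, wild type replicate 2 had 93.1% at 243 reads and the shared file 91.0%. On chromosome 7 at 38301801 to 38302000, 0 of 44 calls were methylated in knockout replicate 2 (upper 95% limit 8.03%), against 55.8% and 56.0% in the others. On chromosome 2 at 51307001 to 51307200, all 16 CpGs were lower, with 13.4% against 53.9%, and the shared file lay between at 31.6%.

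**Figure D4:**
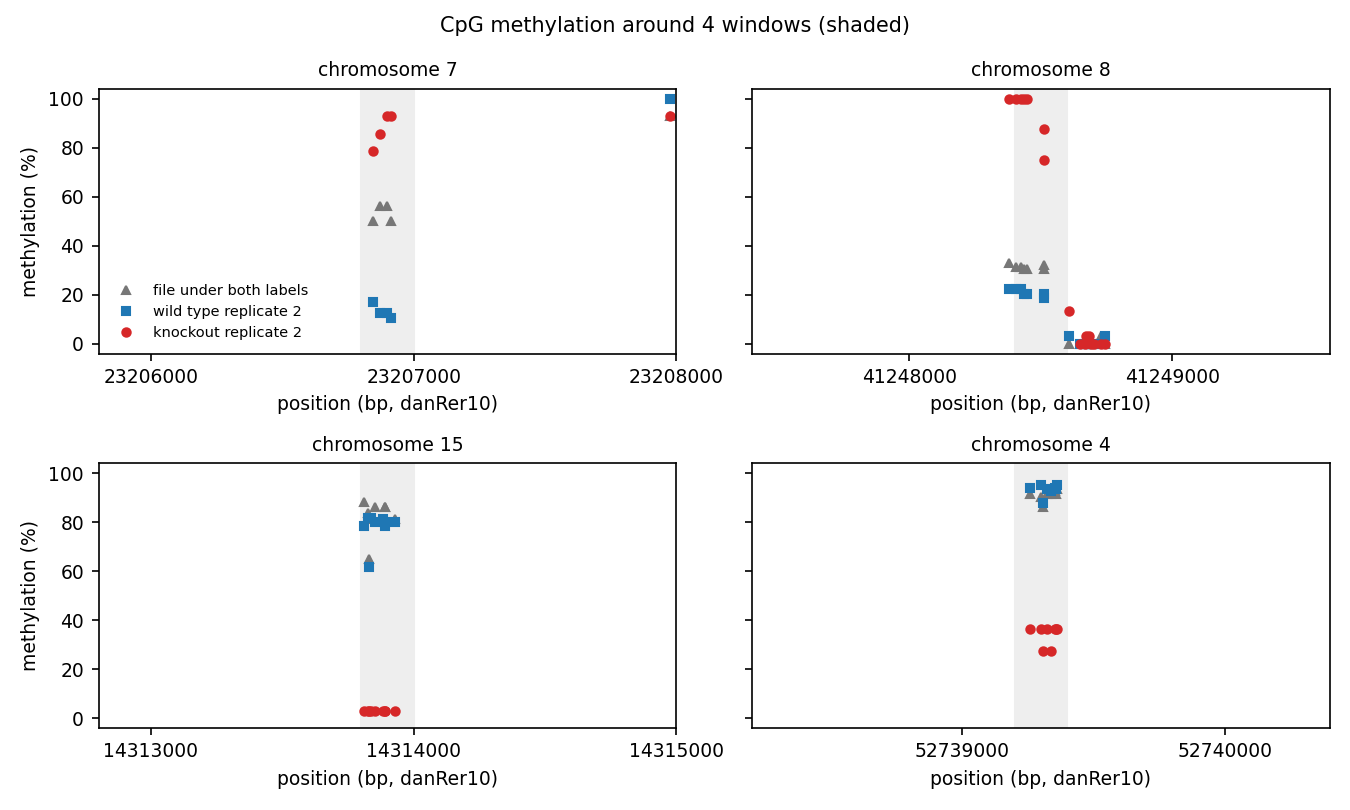
Methylation of single CpGs in percent (vertical axis) by danRer10 position in bp (horizontal axis) around 4 named windows (shaded), 2 higher and 2 lower in knockout replicate 2, with 1 symbol per CpG and distinct library. In the window on chromosome 15 the level was 3.03% in knockout replicate 2 and 78.1% in wild type replicate 2, and in the window on chromosome 8 it was 93.8% and 20.7%.

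Single CpGs were compared by the same rule. Of the 935663 CpGs, 14114 were at least 20 points higher in knockout replicate 2 than in wild type replicate 2 and 9165 lower. Against the shared file, 8253 were higher and 8112 lower in knockout replicate 2, and the shared file had 8473 above wild type replicate 2 and 4782 below it. At least 20 points from both other libraries, knockout replicate 2 had 3388 CpGs above and 4286 below. Fisher's exact test on the reads of these libraries called 191 CpGs higher and 53 lower at a Benjamini-Hochberg adjusted p below 0.05, and 2742 windows higher and 883 lower. The same test on windows called 1922 higher and 1079 lower in the shared file than in wild type replicate 2, and 2464 and 1429 in knockout replicate 2 against the shared file.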

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

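The tests of the identical files, of conversion, of wild type replicate 2, of the tet genes and of coverage were chosen after the results they bear on had been seen.

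CpGs with 1 to 9 reads, which the main comparisons left out, had a higher level in knockout replicate 2 than in both other libraries: 86.5% (95% interval 86.4 to 86.5) against 85.6% in wild type replicate 2 and 85.1% in the shared file. Those with 5 reads or more in all 3 libraries entered 1 alternative of the coverage minimum. Incomplete conversion did not account for it, as unconverted lambda cytosines differed by -0.0095 points between knockout replicate 2 and wild type replicate 2. Each library lists different CpGs in this range. At the 1311417 CpGs with 1 to 9 reads in every library, knockout replicate 2 lay 0.0927 points above the shared file with reads summed, which is what different CpGs would give. An unweighted mean over the same CpGs, added after that value was seen because libraries of unequal depth weight CpGs unequally, gave 0.596 points above the shared file and 0.816 above wild type replicate 2. At CpGs with 1 read in every library, which all count equally, knockout replicate 2 lay 0.806 points above the shared file and 1.101 above wild type replicate 2. At 2 to 4 reads in every library it lay 0.419 and 0.701 points above them, and at 5 to 9 reads 0.351 and 0.481. Different CpGs may thus explain part of the gap. The bound of 0.5 points above both, set beforehand without naming a weighting, was passed by the unweighted mean and at 1 read. It was not passed with reads summed or in the other 2 ranges, so the explanation stays open.

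The file of knockout replicate 1 matched that of wild type replicate 1 in 100% of lines. Libraries that merely agree within sampling noise were excluded, since no other pair had equal counts at more than 1.89% of well-covered CpGs. The values are in line with 1 file deposited under both labels. Which embryos it came from was not tested, and no biological explanation applies.

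The 240 windows in which knockout replicate 2 lay at least 20 points above both other libraries were weighed against technical explanations. Lower depth was argued against by the count at equal depth, 4.92 times the highest count of another library. Counting noise, drawn 100 times with all CpGs of a window on the same reads, gave at most 173 such windows and on average 412 below both, where 59 were seen. With CpGs drawn independently, 20 times, it gave at most 7. The draws on the same reads were noisier than the data in the lower direction, so their count above both is no sure noise level. Noise alone gives each library a like count at equal depth, where 246, 50 and 29 windows above both others were seen for knockout replicate 2, the shared file and wild type replicate 2. Windows below both numbered 66, 72 and 158, so in that direction wild type replicate 2 stood apart. Noise may have made many of the windows without giving these unequal counts. Incomplete conversion (-0.0095 points on lambda) and a variant at 1 CpG (97.5% of windows kept 10 points without the CpG that differed most) were also argued against as the whole cause.

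For the 240 windows, the part of wild type replicate 2 standing apart was not decided. They were chosen to lie at least 20 points above the shared file too, so that distance holds by definition and tests nothing. Without wild type replicate 2, 490 windows lay 20 points above the shared file and 164 below, an excess that does not involve wild type replicate 2. Of the windows 20 points above wild type replicate 2, 69.0% lay 10 points above the shared file too. Choosing windows on knockout replicate 2 favours that share, so it decides nothing. Another 4 explanations cannot be told apart for the 240 windows. A uniform shift of the library stays open because windows above both others were 1.98 times those below at equal medians, between the bounds set beforehand. At a size of 10 points the direction turned at equal medians, with 1039 above and 1208 below, against 1342 and 843 as deposited. At 30 points it did not turn, with 46 above and 10 below at equal medians. Alleles or copies that differ between embryos stay open because 9.58% of the windows changed coverage over 2-fold, while windows within 1.5-fold still gave 175 above and 46 below. The 59 windows below both others had a like share, 10.2%. Named windows were not tested for this as a set, and several had far fewer reads per CpG in knockout replicate 2 than in wild type replicate 2. Loss of the tet genes, which may raise methylation, rests on 1 distinct knockout library. In the edgeR fit with 1 library set against 2, knockout replicate 2 had 4 windows called higher and the highest other choice had 0. In 1 of the 3 choices the count was as large, the real one included, and 3 choices are too few for a share under 0.05.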

How the results depend on the processing

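Fits with 1 library against 2, thinning, equal medians, the demand to lie apart from both others and the coverage limit were chosen after seeing the data. No paired analysis was possible because both files of replicate number 1 are identical, so only 1 pair of distinct libraries exists. Not run were the replicate block, the fits of 4 libraries, and the alternatives for promoters, gene bodies, genomic features and gene lists.

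Counts of windows higher and lower (665 and 174) were within 1.5 times of the main counts with a coverage maximum, at 100 and 500 bp, at equal depth, at equal medians and within the coverage limit. They were 1590 and 797 at 5 reads, of 185508 windows tested, and 2017 and 890 with 1 CpG per window or more, of 203166. At 20 reads they were 315 and 45, of 84359 windows. The main counts were of 134500 windows, so these counts changed by larger factors than the number of windows did. The share of windows counted thus also depended on the reads per CpG and the CpGs per window. The counts were 4043 and 1820 at 10 points, 2742 and 883 by Fisher's exact test, 240 and 59 apart from both others, and 4 and 2 by edgeR with the shared file read as wild type. They were 0 and 0 by edgeR with it read as knockout, by limma with and without equal medians, and by the quasi-binomial model. With knockout replicate 2 as the lone library, edgeR, limma without equal medians and the quasi-binomial model recovered no simulated change at an adjusted p below 0.05 either. That simulation was noisier than the data. Leaving out 1 library gave 233 to 490 higher and 62 to 164 lower. Here and below, without knockout replicate 2 the shared file is set against wild type replicate 2. Without wild type replicate 2, knockout replicate 2 is set against the shared file. Without either replicate 1, the shared file is averaged into the other group. These ranges thus change the comparison and do not test the main pair with a library removed. The lowest count of higher windows was without knockout replicate 2, and the lowest of lower windows without wild type replicate 1.

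Single CpGs higher and lower (14114 and 9165) were 37782 and 29988 at 5 reads, 4629 and 2237 at 20 reads, 191 and 53 by Fisher's exact test, 0 and 0 by limma, and 3388 and 4286 apart from both others. Leaving out 1 library gave 6509 to 8473 and 2937 to 8112, the first lowest without knockout replicate 1 and the second without wild type replicate 1.

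The mean difference of 0.635 points was 0.407 with reads summed, 0.444 over every CpG with 10 reads in that library (where the shared file, at 86.1%, stood above both others), and 0.143 to 0.564 with 1 library left out. In the class below 20% it was 0.0534 at 5 reads, 0.285 with the class defined without knockout replicate 2, and 0.0013 to 0.0289 with 1 library left out. In the class of 20 to 80% it was 2.35 with borders of 10 and 90%, 5.19 with that definition, and 1.25 to 2.77. In the class above 80% it was 0.473, 0.424, and 0.0982 to 0.509. With the class defined without knockout replicate 2, wild type replicate 2 both sets the class and enters the difference, which can by itself move these values. By density, leaving out 1 library gave 0.0898 to 0.926 (1 to 3 CpGs), 0.119 to 0.770 (4 to 7), 0.151 to 0.518 (8 to 14) and 0.0575 to 0.218 (15 or more). With reads summed the last 2 were 0.438 and -0.198, a reversed sign; the cause was not tested. Each mean kept its sign under the other alternatives. Among the left-out libraries, the lowest mean was without wild type replicate 2 in the class below 20% and at 15 or more CpGs, and without knockout replicate 2 in the others. The number of windows or CpGs tested does not account for all of the change in counts, and the cause of these changes was not tested.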

Other observations

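All tests here were chosen after the data were seen. With the shared file read as wild type, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4 windows higher and 2 lower in knockout replicate 2, and 5928 and 2261 at an unadjusted p below 0.05. limma and the quasi-binomial model called 0, with 4900 and 3052 windows unadjusted by limma, 4975 and 3591 by limma at equal medians, and 3543 and 1700 by the quasi-binomial model. No single chance level holds for these unadjusted counts, because the tests differed on unchanged simulated windows. There the quasi-binomial model passed a smaller share at that p than edgeR or limma did. The unadjusted counts alone therefore do not show a difference between the groups. With wild type replicate 2 as the lone library limma gave 2468 and 3781 windows unadjusted, and with the shared file 3139 and 2021. edgeR gave 2456 and 3053, and 1508 and 1911. Of the 6 windows called, 5 were among the named windows of the report, and the other lay on chromosome 7 at 68039601 to 68039800, with 94.9% in knockout replicate 2, 64.3% in wild type replicate 2 and 56.0% in the shared file (adjusted p = 0.0469). This window was picked after its values were seen.

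In 2 of these 6 windows, both on chromosome 4, the directions were opposite, although they lie within the same bin of 50000001 to 60000000. In that bin knockout replicate 2 had 3 windows above both others and 2 below both.

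CpGs 1 to 200 bp outside the 59 windows in which knockout replicate 2 lay below both other libraries differed by -10.5 ± 2.16 points (SEM over 52 windows) from wild type replicate 2, and some of them can lie on the same reads as the window.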
